A study of Schizosaccharomyces pombe with 10 samples.

How the data were processed

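The data are read counts per gene from RNA-seq of total RNA (TRIzol extraction, Illumina libraries) of Schizosaccharomyces pombe strain PT286, 10 libraries in 5 groups of 2. Cells were pre-cultured for 16 h in YES at 30 °C and treated for 8 h with camptothecin (20 µM), hydroxyurea (10 mM), methyl methanesulfonate (0.02 %) or phleomycin (5 µg/mL), and untreated cells served as controls. The authors deposited 1 table of raw counts with 1 column per library, made with HISAT2 and StringTie per the submitters' processing notes. The versions and roles of these tools, the genome build, the annotation, the strand setting and the counting tool are not given in the sources used here. Values are whole numbers, and no scaling had been applied.

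Library totals ran from 37301356 to 48598533 counts. Counting error alone is small at that depth, and reads without molecular identifiers are not independent molecules. Nothing in the sources states that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The replicate numbers did not pair libraries across groups (correlations between groups of the difference between replicates ran from -0.053 to 0.037), so no block was used except as an alternative.

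The 6661 IDs of the table were looked up in assembly ASM294v3 of the species, a reference the authors do not name, for symbols and for which features neighbour or overlap each other: 6540 matched by locus tag, 4 by synonym, and 117 did not match. No coordinates were used in any other way. Sequences were compared with blastn 2.17.0+, and features at least 95 % identical to another over 50 % or more of their length are called near-identical copies. A feature covered by other features over 75 % or more of its span is called covered, a limit chosen after the data were seen.

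Counts were fitted with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with TMM factors (0.944 to 1.09) in 1 model of the 5 groups, after filterByExpr with its default settings, which left 5734 features (4718 protein-coding and 1016 non-coding). The fit had 5 residual degrees of freedom and a common dispersion of 0.000488. Each agent was compared with untreated cells (4 comparisons) and with each other agent (6 comparisons). The p-values are two-sided and Benjamini-Hochberg adjusted over the features tested in a comparison, with a threshold of 0.05, and "rose" and "fell" are used of features past it. Standard errors were derived from the test, as the absolute log2 fold change divided by the square root of its F statistic. They can be too small for large changes that start from few reads. The fit was tested on simulated data with 200 changed features: it recovered 80 to 88 % of those changed 1.25-fold and 94 to 98 % of those changed 2-fold, with 7 to 16 false calls among 5534 unchanged features. These data were drawn from the fitted model itself, with the common dispersion for every feature. At few reads that is close to counting noise, and the real replicates differed by more. The figures therefore do not measure recovery or false calls in the real data.

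Named genes were taken by a rule: among features past the threshold, with both treated libraries on 1 side of both untreated ones and a mean of 10 CPM or more in the higher group, the 6 protein-coding genes with a symbol that rose most and the 6 that fell most, and the 3 non-coding features at each end. Up to 4 members of each list with the smallest adjusted p were added, as were cdc22, suc22, spd1, cdt2, rad52, ctp1, rad54, cdc18, mik1, ctt1, hsp9, gpd1, hsp16 and sme2 in every comparison; 1 further gene of this fixed set is not reported here. All 474 named results past the threshold had both treated libraries on 1 side of both untreated ones, which the rule required of the largest rises and falls. The gene ctp1 had too few counts to be tested.

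The lists were MBF-regulated G1/S genes, ribonucleotide reductase and its regulation, DNA damage checkpoint, homologous recombination, other repair (excision, mismatch and end joining), induced core stress response, Pap1-dependent genes, heat shock proteins and chaperones, cytosolic ribosomal proteins, ribosome biogenesis with RNA polymerase I, histones, mitosis with cell separation, mating with meiosis, nitrogen starvation, glucose-repressed genes, glycolysis, respiration, iron, phosphate, proteasome with ubiquitin, amino acid with sulphur metabolism, purines with pyrimidines, telomeric genes, Tf2 retrotransposons, heterochromatin, named long non-coding RNAs, all long non-coding RNAs, and antisense RNAs. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, Benjamini-Hochberg adjusted over lists of 3 or more measured members in the 4 comparisons, beside camera with an estimated correlation and fry. Member counts refer to tested members, and a second count, where given, is adjusted over the list alone. The names lhs1, hch1, krr1, nop7, ssf1, noc2, dbf2, matPc, matMc, matPi, matMi, aox1, mts1, mts2, aro3 and fui1 were not found.

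Non-coding features were set against 10000 random sets of protein-coding genes matched on mean level. Changes shared by the 4 comparisons were set against independent lists and 20 simulations of unchanged groups with the same controls, and covariances of log2 fold changes were computed with the same or with different untreated libraries. Log2 fold changes of a non-coding feature and an overlapping gene were correlated by Spearman's rho across pairs against 10000 random pairings. The other sets of pairs were set against 1000 random pairings each. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 was used for summaries and figures.

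The groups, comparisons, tests, lists, rule for named genes and most alternatives were chosen before the data were examined. These alternatives were no filter, a mean of 5 CPM or more, DESeq2 1.42.0 size factors in edgeR, quantile normalization with voom, a replicate block, the 4 compared libraries alone, DESeq2's Wald test, adjustment within the class, a fold threshold of 2, each library left out, other list tests and other sets of pairs. Library totals alone as scaling, leaving out covered features, and 2-fold counts under each setting were added after the data were seen.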

Results

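Fission yeast (Schizosaccharomyces pombe, strain PT286) were grown for 16 h in YES, a rich yeast extract medium, and then exposed for 8 h to 1 of 4 agents that damage DNA or stop its copying. Camptothecin (20 µM) traps topoisomerase I on DNA, hydroxyurea (10 mM) inhibits ribonucleotide reductase, methyl methanesulfonate (MMS, 0.02 %) alkylates DNA, and phleomycin (5 µg/mL) breaks its strands. Untreated cells formed the fifth group, and the labels do not say whether they were kept for the same 8 h. Each group had 2 RNA-seq libraries made from total RNA, 10 in all, with library totals of 37301356 to 48598533 counts. The series sets the long non-coding RNAs and mRNAs of treated cells beside those of untreated cells. The table held 6661 features, of which 5132 were protein-coding and 1529 non-coding, and 5734 passed the filter on low counts and were tested. Levels are given as CPM, counts scaled to a common library total, as mean ± SD of the 2 libraries of a group, and log2 fold changes, treated over untreated, are given ± SE. Counts of list members adjusted over the list alone equalled those over all features unless given beside them.

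The 2 libraries of each group lay close together. On the first principal component, which held 52.4 % of the variance, untreated cells stood at -42.5 and -42.4, camptothecin at -18.8 and -19.9, hydroxyurea at 9.63 and 9.34, MMS at 20.5 and 20.4, and phleomycin at 31.8 and 32.0. Replicates differed by more than counting noise, with a chi-square per feature of 3.35 to 3.71, and technical repeats can differ by more than counting noise too. The value changed little with level, from 2.70 to 3.01 for features with few reads to 2.95 to 3.18 for those with many, so whether the pairs are separate cultures stays open. The variation between libraries beyond counting noise, as the square root of the common dispersion fitted over all groups, was 2.21 %. Of tested features, 71.2, 79.1, 80.4 and 82.9 % passed the threshold under camptothecin, hydroxyurea, MMS and phleomycin. Features that also changed 2-fold or more are therefore counted separately. Non-coding features took 6.18 and 6.23 % of counts in untreated cells, 8.60 and 8.68 % with camptothecin, 6.87 and 6.92 % with hydroxyurea, 8.49 and 8.53 % with MMS, and 7.32 and 7.35 % with phleomycin. A few members weigh heavily in this share: SPNCRNA.1095 alone held 2.20 % in untreated cells and 3.83 and 3.81 % with MMS. The share of the mitochondrial genome was 3.16 and 3.11 % in untreated cells and lay between 2.54 and 2.76 % in the 8 treated libraries.

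**Figure D1:**
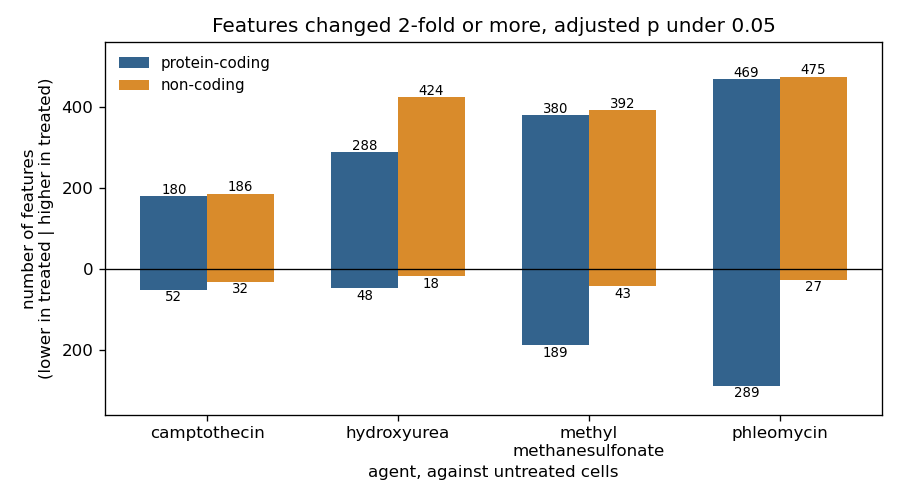
Number of protein-coding and non-coding features (bars, with the count at each bar) that passed the threshold and changed 2-fold or more against untreated cells, higher in treated cells above the line and lower below it, 2 libraries per group. More features rose than fell under each agent, most with phleomycin (469 protein-coding and 475 non-coding up, 289 and 27 down). Quantile normalization narrows this excess to between 54.1 and 62.2 % rising but does not turn it.

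Many genes had almost no counts where other annotated features covered them. The 2187 protein-coding genes that no other feature overlaps had a median of 95.6 CPM, and the 388 wholly covered by features of the opposite strand alone had a median of 0.0164 CPM. Of the 399 protein-coding genes under 0.1 CPM, 318 were covered for 95 % or more of their annotated span. Values of named features covered for 75 % or more are uncertain: fub2, wsp1, rad52, ctp1, ddr48, eno102, pho1, pho84, SPNCRNA.868, SPNCRNA.873, SPNCRNA.1273, SPNCRNA.1314 and SPNCRNA.1514. The same holds for rad3 and alr2, covered for 66.0 and 63.7 %, and for features with a near-identical copy elsewhere in the genome: the Tf2 elements, ftm2, ftm6, meu3, rpl302, rps502, SPNCRNA.232, SPNCRNA.359 and SPNCRNA.362. Antisense features, such as cti6-antisense-1, are uncertain too because no source states that counting used the strand.

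**Figure D2:**
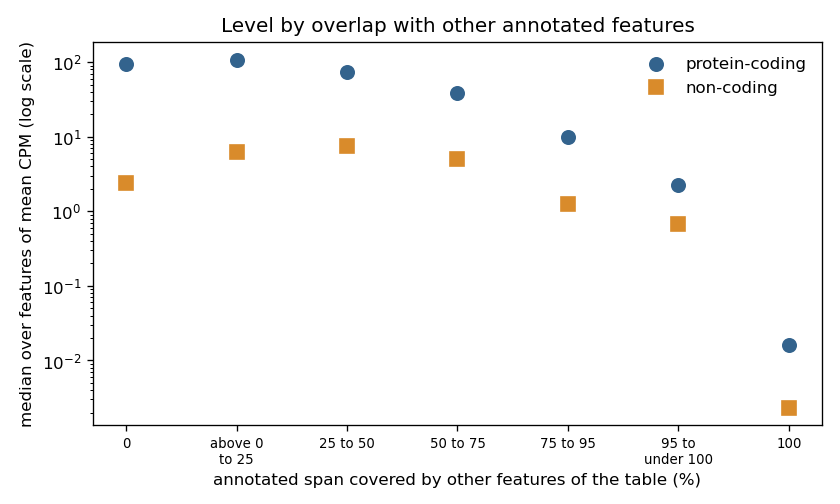
Median over features of the mean CPM of all 10 libraries (log scale), by the percent of a feature's annotated span that other features of the table cover, for protein-coding genes (circles) and non-coding features (squares). Protein-coding genes fall from a median of 95.6 CPM without overlap to 0.0164 CPM when wholly covered.

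Camptothecin gave the fewest 2-fold changes of the 4 agents. The nitric oxide dioxygenase gene yhb1 rose 10.4-fold (185 ± 1.55 to 1916 ± 19.1 CPM, log2 fold change 3.37 ± 0.021, adjusted p = 5.21e-77). A larger rise was that of cmt2 (109 ± 0.636 to 2719 ± 8.34 CPM, log2 4.65 ± 0.022). The copper-zinc superoxide dismutase gene sod1 fell (900.3 ± 8.89 to 238 ± 2.65 CPM, log2 fold change -1.92 ± 0.019, adjusted p = 2.34e-65). Also lower were the iron transporter genes str1 (-2.33 ± 0.030) and str3 (-3.06 ± 0.11), the peptide transporter gene ptr2 (-2.61 ± 0.042), the hexose transporter gene ght3 (-2.13 ± 0.082) and the flocculin gene pfl7 (-2.55 ± 0.10). In all, 2021 features rose and 2059 fell, 366 and 84 of them by 2-fold or more. Under quantile normalization the latter counts were 230 and 140. Some large rises among protein-coding genes with a symbol are uncertain, since ftm6 (7.71 ± 0.33) and ftm2 (5.70 ± 0.25) have near-identical copies and fub2 (5.96 ± 0.18) and wsp1 (4.54 ± 0.16) are covered by other features.

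Of the lists of DNA repair and replication genes, only that of ribonucleotide reductase passed against other genes under camptothecin, and it did not with an estimated correlation (adjusted p = 0.0973). By fry, which sets a list against no other genes, the checkpoint (adjusted p = 0.000186), recombination (8.62e-05) and other repair lists (0.000797) passed upward and the MBF list downward (0.0281). The recombination gene rad54 rose (47.4 ± 2.56 to 89.7 ± 0.628 CPM, log2 fold change 0.92 ± 0.042, adjusted p = 4.16e-29), and the replication licensing gene cdc18 fell (37.03 ± 0.328 to 18.9 ± 0.541 CPM, log2 fold change -0.97 ± 0.061, adjusted p = 2.27e-22). All 7 measured genes of ribonucleotide reductase and its regulation rose, with a median log2 fold change of 0.32 (adjusted p = 0.0115, or 0.0973 with an estimated correlation). Within it the large subunit gene cdc22 moved by 0.063 ± 0.019, the small subunit gene suc22 by 0.32 ± 0.017, the inhibitor gene spd1 by 0.24 ± 0.037 and cdt2, whose product targets Spd1 for destruction, by 0.11 ± 0.042. Of the 19 genes under MBF, the factor of the G1/S transition, 8 rose, 7 fell and 4 did not pass, adjusted p = 0.881. Among them pof3 (1.20 ± 0.086) and cdc6 (0.55 ± 0.042) rose, while cdc18 (-0.97 ± 0.061), rep2 (-0.74 ± 0.044) and mik1 (-0.30 ± 0.053) fell. In the checkpoint list of 17 genes 6 rose, 4 fell and 7 did not pass, adjusted p = 0.259. Rises included the 14-3-3 genes rad24 (0.66 ± 0.017) and rad25 (0.36 ± 0.021) and the clamp loader gene rad17 (0.62 ± 0.051). Of 26 homologous recombination genes, 15 rose, 3 fell and 8 did not pass, adjusted p = 0.198. Of 37 other repair genes, 10 rose, 9 fell and 18 did not pass, adjusted p = 0.597. Rises included the translesion polymerase gene eso1 (0.86 ± 0.030) and the mismatch repair gene pms1 (0.94 ± 0.035).

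Biosynthesis and carbon source genes fell on balance under camptothecin; of the 6 lists that follow, amino acid, mitosis and histone genes did not pass with an estimated correlation. Genes of amino acid and sulphur metabolism had a median log2 fold change of -0.23 (adjusted p = 6.26e-05, or 0.0761 with an estimated correlation). Of 47, 9 rose, 29 fell and 9 did not pass, among them lys4 (-1.16 ± 0.017) of lysine synthesis and sua1 (-1.09 ± 0.021) and met17 (-1.46 ± 0.030) of sulphur assimilation. Glucose-repressed genes had a median log2 fold change of -0.42 (adjusted p = 7.99e-06, or 0.0276 with an estimated correlation). Of 22, 3 rose, 16 fell and 3 did not pass. Among these were the malic enzyme gene mae2 (-1.39 ± 0.018), the aldehyde dehydrogenase gene atd1 (-1.20 ± 0.017) and the invertase gene inv1 (-1.21 ± 0.022). Genes of purine and pyrimidine synthesis had a median log2 fold change of -0.40 (adjusted p = 1.95e-06, or 0.0452 with an estimated correlation). Of 25, 2 rose, 20 fell and 3 did not pass. Among these were gua2 (-0.99 ± 0.022) and ade3 (-0.59 ± 0.019); the list also holds hmt2, a sulphide oxidoreductase gene matched by an older name. Ribosome biogenesis genes had a median log2 fold change of -0.23 (adjusted p = 0.000143, or 0.0268 with an estimated correlation). Of 79, 14 rose, 55 fell and 10 did not pass (15 up and 55 down adjusted over the list alone). Examples were utp10 (-0.79 ± 0.020), nop58 (-0.64 ± 0.017) and the RNA polymerase I gene nuc1 (-0.71 ± 0.020). Genes of mitosis and cell separation had a median log2 fold change of -0.15 (adjusted p = 0.0181, or 0.215 with an estimated correlation). Of 31, 9 rose, 16 fell and 6 did not pass (9 up and 17 down adjusted over the list alone). Falls included the cell separation gene adg1 (-1.498 ± 0.042) and the glucanase gene agn1 (-1.11 ± 0.034). Histone genes had a median log2 fold change of -0.46 (adjusted p = 0.000236, or 0.0609 with an estimated correlation). Of 8, 1 rose, 6 fell and 1 did not pass (2 up and 6 down adjusted over the list alone). Falls included hta2 (-0.89 ± 0.022), hht1 (-0.75 ± 0.018) and hhf1 (-0.61 ± 0.017).

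Other groups went both ways under camptothecin. Of 115 genes of mating and meiosis, 54 rose, 24 fell and 37 did not pass, adjusted p = 0.0542. Rises included the meiotic recombination gene rec10 (2.43 ± 0.057) and the pheromone receptor gene mam2 (1.34 ± 0.044). In the iron list 7 rose, 9 fell and 4 did not pass, adjusted p = 0.404, the siderophore synthetase gene sib1 (0.92 ± 0.018) rising while the ferroxidase gene fio1 (-1.29 ± 0.039) and the iron-sensing repressor gene fep1 (-1.20 ± 0.040) fell. Among 35 core stress genes 11 rose, 21 fell and 3 did not pass, adjusted p = 0.467. A rise was seen in the metallothionein gene zym1 (1.27 ± 0.025). The trehalose phosphate synthase gene tps1 (-0.69 ± 0.017), the catalase gene ctt1 (-0.11 ± 0.019) and the glycerol phosphate dehydrogenase gene gpd1 (-0.18 ± 0.017) fell. Of 27 chaperone genes 12 rose, 12 fell and 3 did not pass, adjusted p = 0.313. The genes ssa1 (0.60 ± 0.017) and hsp16 (0.54 ± 0.017) rose and pss1 (-0.93 ± 0.016) fell. The stress gene hsp9 had a log2 fold change of -0.018 ± 0.015 (adjusted p = 0.28). Of 24 oxidative stress genes under Pap1, 9 rose, 11 fell and 4 did not pass, adjusted p = 0.313. Glycolysis genes (18) did not pass as a list: 9 rose, 5 fell and 4 did not pass (10 up and 5 down adjusted over the list alone), adjusted p = 0.0787, with gpd3, a glyceraldehyde phosphate dehydrogenase gene, up by 1.82 ± 0.024 and tpi1 at -0.71 ± 0.015. The remaining lists did not pass either. Of 122 ribosomal protein genes 47 rose, 59 fell and 16 did not pass (48 up and 59 down adjusted over the list alone), adjusted p = 0.415. Of 33 respiration genes 17 rose, 7 fell and 9 did not pass, adjusted p = 0.157. Of 42 proteasome and ubiquitin genes 18 rose, 11 fell and 13 did not pass, adjusted p = 0.22. Starvation genes came to 52, of which 19 rose, 17 fell and 16 did not pass, adjusted p = 0.81. In the phosphate list of 13 7 rose and 6 fell, adjusted p = 0.445. In the heterochromatin list of 22 8 rose, 8 fell and 6 did not pass, adjusted p = 0.907. In the telomeric list of 19 6 rose, 7 fell and 6 did not pass, adjusted p = 0.774.

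Non-coding RNAs rose on balance with camptothecin, but this direction depends on the scaling. Long non-coding RNAs had a median log2 fold change of 0.28 (adjusted p = 0.0212, or 0.0112 with an estimated correlation). Of 1015, 383 rose, 131 fell and 501 did not pass (360 up and 117 down adjusted over the list alone), and under quantile normalization the median was -0.04, with 228 up and 209 down. With a replicate block the list did not pass (adjusted p = 0.0666). Named non-coding RNAs had a median log2 fold change of 0.75 (adjusted p = 0.000275, or 0.148 with an estimated correlation). Under quantile normalization it was 0.39 (19 up, 5 down). Of 44, 27 rose, 3 fell and 14 did not pass, among them the telomerase RNA ter1 (217 ± 0.850 to 449.5 ± 8.77 CPM, log2 1.05 ± 0.022), prl53 (1.11 ± 0.015), omt3 (3.61 ± 0.073) and sme2, the meiotic RNA that binds Mei2 (1.01 ± 0.083). Among non-coding features at 10 CPM or more, prl14 (6.04 ± 0.29), SPNCRNA.446 (6.01 ± 0.20) and SPNCRNA.175 (4.59 ± 0.20) rose most, and SPNCRNA.293 (-2.04 ± 0.13), SPNCRNA.781 (-1.31 ± 0.10) and SPNCRNA.1310 (-1.25 ± 0.15) fell most. All 3 measured Tf2 retrotransposons rose, with a median log2 fold change of 1.59 (adjusted p = 0.00155, or 0.0847 with an estimated correlation), with Tf2-7 (45.4 ± 0.233 to 137 ± 0.523 CPM, log2 1.59 ± 0.039) at the highest level. The list held 13 elements, and only these 3 were tested, here and under the other agents. Each has near-identical copies elsewhere, so the 3 may not be independent members, as the preset correlation nearly assumes.

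Hydroxyurea raised most genes of S phase entry that MBF controls. The large ribonucleotide reductase subunit gene cdc22 rose 2.96-fold (496 ± 2.45 to 1468 ± 12.4 CPM, log2 fold change 1.57 ± 0.018, adjusted p = 1.56e-60). The inhibitor gene spd1 fell (114 ± 0.308 to 64.1 ± 1.61 CPM, log2 fold change -0.83 ± 0.039, adjusted p = 2.07e-28). The glyceraldehyde phosphate dehydrogenase gene gpd3 rose 8.30-fold (98.9 ± 1.91 to 822 ± 23.3 CPM, log2 fold change 3.05 ± 0.023, adjusted p = 5.67e-71). The invertase gene inv1 fell 3.40-fold (761 ± 14.2 to 224 ± 5.12 CPM, log2 fold change -1.76 ± 0.023, adjusted p = 4.24e-58). In all, 2311 features rose and 2225 fell, 712 and 66 of them by 2-fold or more, or 303 and 208 under quantile normalization. With library totals alone as the scaling, the median of all features moved by 0.184 (log2), and 3112 features rose and 1485 fell, 67.7 % rising in place of 50.9 %.

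MBF genes had a median log2 fold change of 0.73 (adjusted p = 6.38e-09, or 0.0188 with an estimated correlation). Of 19, 16 rose and 3 did not pass. Beside cdc22 these included tos4 (1.497 ± 0.026), cdt2 (0.95 ± 0.040), the cohesin gene rad21 (0.73 ± 0.031), cdc18 (0.84 ± 0.053) and mik1 (0.80 ± 0.050), whose product restrains the mitotic kinase. Ribonucleotide reductase genes had a median log2 fold change of 0.36 (adjusted p = 0.000753, or 0.0636 with an estimated correlation). Of 7, 5 rose and 2 fell, suc22 rising by 0.36 ± 0.017, and the median was 0.65 under quantile normalization. Of 17 checkpoint genes 8 rose, 4 fell and 5 did not pass, adjusted p = 0.135, with the ATM kinase gene tel1 (0.72 ± 0.031) and rad25 (0.48 ± 0.021) among the rises. Of 26 recombination genes 18 rose, 4 fell and 4 did not pass, adjusted p = 0.0935. Examples were rad54 (1.04 ± 0.041) and sfr1 (0.87 ± 0.065), while rad52 rose by 0.27 ± 0.12 and turned negative under quantile normalization. Of 37 other repair genes 17 rose, 7 fell and 13 did not pass (16 up and 7 down adjusted over the list alone), adjusted p = 0.193. Examples were eso1 (0.66 ± 0.031) and msh3 (0.58 ± 0.037).

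Genes of ribosomal proteins, nucleotide synthesis and histones fell on balance under hydroxyurea, although none of these 3 lists passed with an estimated correlation. Ribosomal protein genes had a median log2 fold change of -0.43 (adjusted p = 2.14e-26, or 0.125 with an estimated correlation). Of 122, 15 rose, 99 fell and 8 did not pass. Examples were rps2402 (-1.07 ± 0.015), rps401 (-1.05 ± 0.015) and rpp102 (-1.16 ± 0.017); a few members (rpp1, rpp21 and rpp40) belong to RNase P, not the ribosome. The 79 ribosome biogenesis genes did not pass as a list, although 19 rose, 45 fell and 15 did not pass, adjusted p = 0.0905. Their median was -0.16, and 0.02 under total count scaling, with falls of nop58 (-0.62 ± 0.017) and nhp2 (-0.58 ± 0.019). Proteasome and ubiquitin genes had a median log2 fold change of -0.25 (adjusted p = 0.00143, or 0.156 with an estimated correlation). Of 42, 7 rose, 29 fell and 6 did not pass. Falls included ubi3 (-0.92 ± 0.016) and ubi5 (-0.80 ± 0.015), which encode ubiquitin fused to ribosomal proteins. Purine and pyrimidine genes had a median log2 fold change of -0.35 (adjusted p = 0.000881, or 0.0636 with an estimated correlation). Of 25, 3 rose and 22 fell. Falls included prs1 (-0.87 ± 0.018) and apt1 (-1.18 ± 0.030), and rises included gua1 (0.76 ± 0.017) and ade10 (0.63 ± 0.019). Scaling moved the medians of 3 of these lists: quantile normalization and total count scaling gave -0.19 (37 up, 75 down) and -0.25 (24 up, 76 down) for ribosomal proteins, -0.062 (12 up, 22 down) and -0.066 (12 up, 20 down) for the proteasome list, and -0.15 (5 up, 15 down) and -0.17 (4 up, 16 down) for purines and pyrimidines. Histone genes had a median log2 fold change of -0.62 (adjusted p = 0.000403, or 0.0609 with an estimated correlation). Of 8, 2 rose and 6 fell, with hhf1 (-0.75 ± 0.017) and hta2 (-0.76 ± 0.021) among the falls. Of 31 mitosis genes 15 rose, 15 fell and 1 did not pass, adjusted p = 0.358. Falls included adg1 (-1.74 ± 0.042), agn1 (-1.36 ± 0.035) and adg3 (-1.14 ± 0.033).

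Stress genes did not rise together under hydroxyurea. Core stress genes had a median log2 fold change of -0.38 (adjusted p = 0.0197, or 0.287 with an estimated correlation). Quantile normalization gave -0.18 (13 up, 20 down) and total count scaling -0.20 (13 up, 21 down). Of 35, 12 rose and 23 fell, the trehalose gene tps1 (-0.97 ± 0.017) and hsp9 (-0.96 ± 0.016) falling while the glutathione transferase gene gst2 rose (776 ± 6.51 to 3220.2 ± 24.3 CPM, log2 2.05 ± 0.016), as did zym1 (1.37 ± 0.025) and ctt1 (0.11 ± 0.019). Chaperone genes had a median log2 fold change of -0.23 (adjusted p = 0.000236, or 0.0636 with an estimated correlation). Of 27, 9 rose, 17 fell and 1 did not pass. Falls included the Hsp110 gene pss1 (-1.17 ± 0.016) and the Hsp90 cochaperone gene aha1 (-0.85 ± 0.020); the list median was 0.0037 under quantile normalization and -0.05 under total count scaling. In single genes hsp16 fell by 0.13 and gpd1 fell by 0.39 on the log2 scale, and both values turned positive under quantile normalization. Of 24 Pap1 genes 11 rose, 9 fell and 4 did not pass, adjusted p = 0.203. The peroxiredoxin gene tpx1 (0.85 ± 0.016) rose while the sulphiredoxin gene srx1 (-1.15 ± 0.033) and apt1 (-1.18 ± 0.030), an adenine salvage gene, fell. Glycolysis genes had a median log2 fold change of 0.48 (adjusted p = 7.93e-05, or 0.3 with an estimated correlation). Of 18, 13 rose and 5 fell. Examples were pyk1 (0.72 ± 0.016) and tdh1 (0.68 ± 0.017), and the hexose transporter gene ght5 (-1.14 ± 0.019) fell. Of 22 glucose-repressed genes 8 rose, 13 fell and 1 did not pass, adjusted p = 0.156. Falls included mae2 (-0.61 ± 0.017) and ght4 (-0.81 ± 0.031), and rises included the galactosidase gene mel1 (1.15 ± 0.158 to 13.5 ± 1.21 CPM, log2 3.55 ± 0.15). In the iron list 10 rose, 6 fell and 4 did not pass, adjusted p = 0.588, str1 (-1.63 ± 0.028) falling and str3 (1.46 ± 0.057) rising.

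Meiotic, telomeric and Tf2 genes rose on balance under hydroxyurea, and of these 3 lists only the meiotic one passed with an estimated correlation. Mating and meiosis genes had a median log2 fold change of 0.38 (adjusted p = 0.00404, or 0.0437 with an estimated correlation). Of 115, 74 rose, 22 fell and 19 did not pass (74 up and 23 down adjusted over the list alone), and the median was 0.18 (47 up, 31 down) under quantile normalization. Rises included mug146 (2.81 ± 0.12), mug15 (2.69 ± 0.10) and rec10 (2.23 ± 0.057). Telomeric genes had a median log2 fold change of 0.32 (adjusted p = 0.0195, or 0.101 with an estimated correlation). Of 19, 13 rose, 3 fell and 3 did not pass, and the median was 0.17 (9 up, 3 down) under quantile normalization and 0.50 (16 up, 1 down) under total count scaling. Among these were the telomere binding gene pot1 (1.47 ± 0.044), ter1 (0.73 ± 0.022) and the flocculin gene pfl9 (2.30 ± 0.15). All 3 Tf2 elements rose, with a median of 1.34 (adjusted p = 0.000322, or 0.0636 with an estimated correlation), Tf2-11 (4.55 ± 0.842 to 34.1 ± 1.04 CPM, log2 2.90 ± 0.10) most. Of 22 heterochromatin genes 12 rose, 6 fell and 4 did not pass, adjusted p = 0.315, chp2 (0.76 ± 0.060) rising and swi6 (-0.29 ± 0.029) falling. Long non-coding RNAs had a median log2 fold change of 0.89 (adjusted p = 2.95e-07, or 0.00136 with an estimated correlation). Of 1015, 676 rose, 67 fell and 272 did not pass (670 up and 66 down adjusted over the list alone). Under quantile normalization this excess shrank to a median of 0.149, with 329 up and 207 down. Named non-coding RNAs had a median log2 fold change of 0.81 (adjusted p = 0.00483, or 0.199 with an estimated correlation). Of 44, 29 rose, 5 fell and 10 did not pass, and the median was 0.35 (21 up, 9 down) under quantile normalization. At 10 CPM or more, meu3 (5.24 ± 0.27), SPNCRNA.987 (3.68 ± 0.21) and SPNCRNA.868 (3.23 ± 0.20) rose most and SPNCRNA.359 (-2.84 ± 0.14), SPNCRNA.232 (-2.33 ± 0.19) and SPNCRNA.362 (-1.39 ± 0.14) fell most. Further large single changes were the rises of nrg1 (5.21 ± 0.281 to 65.8 ± 0.531 CPM, log2 3.66 ± 0.073) and osr1 (28.6 ± 0.574 to 192 ± 0.951 CPM, log2 2.74 ± 0.031) and the falls of wwm3 (1804 ± 42.6 to 554 ± 5.24 CPM, log2 -1.70 ± 0.018), ddr48 (-1.67 ± 0.064) and the sulphate transporter gene sul2 (-1.56 ± 0.032). The lists left did not pass. In amino acid metabolism 18 rose, 24 fell and 5 did not pass (19 up and 24 down adjusted over the list alone), adjusted p = 0.313. In respiration 11 rose, 18 fell and 4 did not pass, adjusted p = 0.624. In the starvation list 20 rose, 19 fell and 13 did not pass, adjusted p = 0.836. In the phosphate list 6 rose, 6 fell and 1 did not pass, adjusted p = 0.993.

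MMS raised genes for taking up iron and haem and for coping with oxidants. The haem uptake gene shu1 went from 12 reads over both untreated libraries to 21211 over both treated ones (0.145 ± 0.0586 to 266 ± 5.84 CPM, log2 fold change 10.79 ± 0.12, adjusted p = 5.78e-63). The siderophore or haem transporter gene str3 rose 44.9-fold (11.9 ± 0.784 to 536 ± 1.41 CPM, log2 fold change 5.49 ± 0.045, adjusted p = 5.5e-70). Likewise gpd3 rose 42.2-fold (98.9 ± 1.91 to 4177 ± 99.7 CPM, log2 fold change 5.40 ± 0.024, adjusted p = 3.76e-85). The peroxiredoxin gene tpx1 rose 5.39-fold (953 ± 6.22 to 5140.4 ± 10.9 CPM, log2 2.43 ± 0.016). Among protein-coding genes with a symbol at 10 CPM or more, those that separate daughter cells fell most, adg1 (203 ± 3.76 to 9.47 ± 0.107 CPM, log2 fold change -4.42 ± 0.055, adjusted p = 6.98e-60) ahead of the glucanase genes eng1 (-2.94 ± 0.054) and agn1 (-2.85 ± 0.040). In all, 2266 features rose and 2343 fell, 772 and 232 of them by 2-fold or more, or 471 and 360 under quantile normalization.

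Iron genes had a median log2 fold change of 0.81 (adjusted p = 1.23e-12, or 0.0204 with an estimated correlation). Of 20, 15 rose and 5 fell, and besides shu1 and str3 the iron permease gene fip1 (3.82 ± 0.052) and its ferroxidase partner fio1 (3.42 ± 0.029) rose. Pap1 genes had a median log2 fold change of 0.52 (adjusted p = 6.74e-15, or 0.0224 with an estimated correlation). Of 24, 20 rose, 3 fell and 1 did not pass. Examples were gst2 (2.97 ± 0.016), the efflux pump gene caf5 (3.78 ± 0.036) and srx1 (2.33 ± 0.028), while apt1 fell by 1.73. Core stress genes had a median log2 fold change of 0.081 (adjusted p = 4.01e-07, or 0.0636 with an estimated correlation). Of 35, 17 rose, 11 fell and 7 did not pass, and the median was 0.25 (22 up, 8 down) under quantile normalization and 0.17 (21 up, 9 down) under total count scaling. Rises included zym1 (2.86 ± 0.024), plr1 (1.32 ± 0.016), hsp9 (0.83 ± 0.015) and ctt1 (0.85 ± 0.019). The value of gpd1 was -0.33 ± 0.017, which turned positive under quantile normalization. Chaperone genes had a median log2 fold change of 0.22 (adjusted p = 0.0101, or 0.122 with an estimated correlation). Of 27, 16 rose, 9 fell and 2 did not pass, and the median was 0.51 (19 up, 6 down) under quantile normalization. Examples were ssa1 (1.15 ± 0.017), hsp16 (1.09 ± 0.017) and hsp20 (1.69 ± 0.028), and also hsp3104 (1.43 ± 0.025), a member of the DJ-1 family rather than a chaperone.

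Most MBF genes rose with MMS, while the recombination list did not pass. MBF genes had a median log2 fold change of 0.54 (adjusted p = 3.2e-05, or 0.0344 with an estimated correlation). Of 19, 17 rose, 1 fell and 1 did not pass. Rises included cdc22 (496 ± 2.45 to 1246 ± 21.7 CPM, log2 1.33 ± 0.018), cdt2 (1.69 ± 0.039), tos4 (1.20 ± 0.026), rad21 (1.14 ± 0.031) and cdc18 (1.14 ± 0.052). Ribonucleotide reductase genes had a median log2 fold change of 0.57 (adjusted p = 0.00225, or 0.0652 with an estimated correlation). Of 7, 5 rose and 2 fell, with suc22 up by 0.57 ± 0.017, spd2 by 1.43 ± 0.040 and spd1 by 0.093 ± 0.037. The recombination gene rad54 rose (47.4 ± 2.56 to 166 ± 0.174 CPM, log2 fold change 1.81 ± 0.040, adjusted p = 3.66e-46). The gene rad52 rose by 1.03 ± 0.11. Of 26 in that list 12 rose, 8 fell and 6 did not pass, adjusted p = 0.22. A fall was seen in rlp1 (-1.08 ± 0.047). Of 17 checkpoint genes 9 rose, 6 fell and 2 did not pass, adjusted p = 0.245. Examples were rad25 (1.29 ± 0.020), the replication checkpoint kinase gene cds1 (0.91 ± 0.048) and mik1 (0.54 ± 0.051) on the rising side. Of 37 other repair genes 14 rose, 10 fell and 13 did not pass, adjusted p = 0.707, with thp1 (0.66 ± 0.032) and rhp42 (0.90 ± 0.049) rising and the endonuclease gene uve1 (-0.96 ± 0.034) falling.

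Ribosomal protein genes fell almost throughout with MMS. Ribosomal protein genes had a median log2 fold change of -0.70 (adjusted p = 4.35e-49, or 0.0636 with an estimated correlation). Of 122, 4 rose, 114 fell and 4 did not pass. Examples were rps2402 (-1.32 ± 0.016), rpl402 (-1.25 ± 0.016) and rpl3201 (-1.31 ± 0.017). Ribosome biogenesis genes had a median log2 fold change of -0.27 (adjusted p = 0.0107, or 0.0636 with an estimated correlation). Of 79, 16 rose, 50 fell and 13 did not pass. Examples were nhp2 (-0.97 ± 0.019) and nop56 (-0.78 ± 0.019). Purine and pyrimidine genes had a median log2 fold change of -0.53 (adjusted p = 1.95e-06, or 0.0276 with an estimated correlation). Of 25, 2 rose, 22 fell and 1 did not pass. Examples were prs1 (-1.26 ± 0.018), ura1 (-0.91 ± 0.016) and apt1 (-1.73 ± 0.031). Mitosis genes had a median log2 fold change of -0.28 (adjusted p = 0.000236, or 0.0973 with an estimated correlation). Of 31, 8 rose, 19 fell and 4 did not pass, with adg2 (-2.23 ± 0.047) and adg3 (-1.84 ± 0.035) beside the genes above. Histone genes had a median log2 fold change of -0.27 (adjusted p = 0.0394, or 0.148 with an estimated correlation). Of 8, 3 rose, 4 fell and 1 did not pass. Falls included hht1 (-0.83 ± 0.018) and hta2 (-0.96 ± 0.022). Glycolysis genes had a median log2 fold change of 0.60 (adjusted p = 0.000145, or 0.306 with an estimated correlation). Of 18, 11 rose, 6 fell and 1 did not pass. Rises included pgi1 (0.82 ± 0.017) and the covered gene eno102 (4.31 ± 0.18), and falls included the transporter genes ght5 (-0.99 ± 0.019) and ght2 (-0.997 ± 0.024). Of 22 glucose-repressed genes 8 rose, 11 fell and 3 did not pass, adjusted p = 0.198, with inv1 (-2.14 ± 0.024) falling and mel1 (4.18 ± 0.14) and dak2 (1.92 ± 0.057) rising.

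Long non-coding RNAs had a median log2 fold change of 0.68 (adjusted p = 0.00366, or 0.00656 with an estimated correlation). Of 1015, 561 rose, 147 fell and 307 did not pass (555 up and 144 down adjusted over the list alone). The median fell to 0.0888 under quantile normalization, with 335 up and 263 down. Named non-coding RNAs had a median log2 fold change of 0.89 (adjusted p = 0.0364, or 0.292 with an estimated correlation). Of 44, 24 rose, 7 fell and 13 did not pass, and the median was 0.38 (19 up, 8 down) under quantile normalization. The named RNAs omt3 (5.45 ± 0.499 to 118 ± 4.41 CPM, log2 4.44 ± 0.070), ter1 (0.78 ± 0.022) and sme2 (1.58 ± 0.081) rose, as did SPNCRNA.1273 (5.12 ± 0.23) and SPNCRNA.1258 (4.24 ± 0.14), while SPNCRNA.359 (-3.11 ± 0.15), SPNCRNA.232 (-2.27 ± 0.19) and SPNCRNA.1314 (-2.16 ± 0.16) fell. All 3 Tf2 elements rose, with a median of 1.86 (adjusted p = 0.00126, or 0.0636 with an estimated correlation). Other large single changes were the rise of osr1 (28.6 ± 0.574 to 1050.0 ± 5.08 CPM, log2 5.20 ± 0.028) and the falls of alr2 (-2.74 ± 0.13) and the M-factor pheromone gene mfm2 (-2.52 ± 0.12). Of 115 meiosis genes 58 rose, 34 fell and 23 did not pass, adjusted p = 0.293. A fall was seen in spo15 (-0.76 ± 0.019) and rises in rec6 (1.54 ± 0.050) and mug35 (1.15 ± 0.033). Of 42 proteasome and ubiquitin genes 27 rose, 7 fell and 8 did not pass, adjusted p = 0.0633, with cdc48 (1.08 ± 0.016) rising and ubi5 (-1.32 ± 0.015) and ubi3 (-1.23 ± 0.016) falling. Of 52 starvation genes 33 rose, 13 fell and 6 did not pass, adjusted p = 0.0912, with ecl1 (2.41 ± 0.055) and isp6 (1.46 ± 0.031) rising and the permease gene aat1 (-1.79 ± 0.019) falling. Respiration did not pass, and 18 rose, 10 fell and 5 did not pass, adjusted p = 0.127. Amino acid metabolism did not either, and 17 rose, 20 fell and 10 did not pass, adjusted p = 0.765. In the heterochromatin list 10 rose, 7 fell and 5 did not pass, adjusted p = 0.616. In the phosphate list 5 rose, 5 fell and 3 did not pass, adjusted p = 0.922. In the telomeric list 9 rose, 6 fell and 4 did not pass, adjusted p = 0.872.

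Phleomycin changed the most features, with falls of histone and ribosome assembly genes. The histone H3 gene hht1 fell 5.06-fold (1027 ± 9.99 to 203 ± 2.17 CPM, log2 fold change -2.34 ± 0.020, adjusted p = 1.13e-68). The cell separation gene adg1 fell further (203 ± 3.76 to 10.5 ± 0.600 CPM, log2 fold change -4.27 ± 0.054, adjusted p = 1.44e-59). The small ribonucleotide reductase subunit gene suc22 rose 2.51-fold (717 ± 0.0149 to 1799 ± 5.73 CPM, log2 fold change 1.33 ± 0.017, adjusted p = 2.24e-59), more than cdc22 (496 ± 2.45 to 727 ± 2.84 CPM, log2 fold change 0.55 ± 0.019, adjusted p = 3.24e-36). The galactosidase gene mel1 rose strongly (1.15 ± 0.158 to 40.4 ± 1.03 CPM, log2 fold change 5.13 ± 0.14, adjusted p = 6.44e-42). The invertase gene inv1 fell (761 ± 14.2 to 149 ± 3.13 CPM, log2 fold change -2.35 ± 0.024, adjusted p = 1.31e-64). In all, 2419 features rose and 2336 fell, 944 and 316 of them by 2-fold or more, or 575 and 487 under quantile normalization.

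All 8 measured histone genes fell with phleomycin, with a median log2 fold change of -1.36 (adjusted p = 3.99e-16, or 0.0112 with an estimated correlation), including hhf1 (-1.94 ± 0.018), hta2 (-1.99 ± 0.023) and hhf2 (-1.29 ± 0.020). Mitosis genes had a median log2 fold change of -0.56 (adjusted p = 0.000172, or 0.0973 with an estimated correlation). Of 31, 9 rose, 18 fell and 4 did not pass, with agn1 (-2.72 ± 0.039), cfh4 (-2.03 ± 0.032) and the glucan synthase gene bgs4 (-1.15 ± 0.018) among the falls. Ribosome biogenesis genes had a median log2 fold change of -0.52 (adjusted p = 6.46e-06, or 0.0188 with an estimated correlation). Of 79, 16 rose, 59 fell and 4 did not pass. Examples were utp10 (-1.39 ± 0.021), nuc1 (-1.22 ± 0.020) and nhp2 (-1.01 ± 0.019). Ribosomal protein genes had a median log2 fold change of -0.32 (adjusted p = 1.48e-09, or 0.306 with an estimated correlation). Of 122, 25 rose, 87 fell and 10 did not pass, and the median was -0.18 (37 up, 77 down) under quantile normalization. Examples were rps2202 (-1.75 ± 0.021) and rpl702 (-1.23 ± 0.017). Purine and pyrimidine genes had a median log2 fold change of -0.62 (adjusted p = 0.000143, or 0.0609 with an estimated correlation). Of 25, 4 rose and 21 fell, prs1 (-1.25 ± 0.018), ura1 (-1.03 ± 0.016) and apt1 (-1.92 ± 0.031) falling and gua1 (0.82 ± 0.017) rising. Glycolysis genes had a median log2 fold change of 0.83 (adjusted p = 1.03e-07, or 0.198 with an estimated correlation). Of 18, 16 rose and 2 fell, with gpd3 (3.56 ± 0.023), pgk1 (1.21 ± 0.017) and gpm1 (0.98 ± 0.016) rising and ght5 (-1.65 ± 0.019) falling. Glucose-repressed genes had a median log2 fold change of -0.38 (adjusted p = 0.00315, or 0.0636 with an estimated correlation). Of 22, 4 rose, 15 fell and 3 did not pass. Among these were ght8 (-1.27 ± 0.018), atd1 (-0.99 ± 0.017) and mae2 (-0.90 ± 0.017). Proteasome and ubiquitin genes had a median log2 fold change of 0.26 (adjusted p = 0.00261, or 0.219 with an estimated correlation). Of 42, 24 rose, 11 fell and 7 did not pass, the proteasome genes pre4 (1.15 ± 0.019) and pre5 (0.85 ± 0.019) and the segregase gene cdc48 (1.01 ± 0.016) rising and ubi3 (-0.83 ± 0.016) falling.

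MBF genes had a median log2 fold change of 0.29 (adjusted p = 0.0364, or 0.126 with an estimated correlation). Of 19, 14 rose, 2 fell and 3 did not pass, among them the mismatch repair gene msh6 (0.88 ± 0.029), tos4 (0.66 ± 0.027) and cdt2 (0.81 ± 0.040), with cdc18 at 0.29 ± 0.054 and mik1 at 0.24 ± 0.051. Ribonucleotide reductase genes had a median log2 fold change of 0.55 (adjusted p = 0.00877, or 0.0931 with an estimated correlation). Of 7, 4 rose and 3 fell, where spd2 (1.57 ± 0.039) rose and spd1 (-0.24 ± 0.038) fell. Of 26 recombination genes 16 rose, 5 fell and 5 did not pass, adjusted p = 0.0933. Rises included rad54 (47.4 ± 2.56 to 125 ± 3.70 CPM, log2 1.39 ± 0.040) and nse1 (0.52 ± 0.025). The gene rad52 had a log2 fold change of 0.16 ± 0.12 (adjusted p = 0.208). Of 17 checkpoint genes 8 rose, 6 fell and 3 did not pass, adjusted p = 0.255, with rad24 (0.91 ± 0.017) and rad25 (0.98 ± 0.021) rising and the mitotic inhibitor gene wee1 (-0.87 ± 0.062) falling. Of 37 other repair genes 18 rose, 8 fell and 11 did not pass, adjusted p = 0.198, with eso1 (0.95 ± 0.030) and thp1 (0.80 ± 0.032) rising and rhp23 (-0.78 ± 0.034) falling. Meiosis genes had a median log2 fold change of 0.36 (adjusted p = 0.0305, or 0.0636 with an estimated correlation). Of 115, 66 rose, 29 fell and 20 did not pass, and the median was 0.092 (52 up, 38 down) under quantile normalization. Rises included mug15 (3.25 ± 0.099), rec10 (2.63 ± 0.056) and mug37 (1.95 ± 0.080).

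Long non-coding RNAs had a median log2 fold change of 0.96 (adjusted p = 0.000188, or 0.00302 with an estimated correlation). Of 1015, 638 rose, 116 fell and 261 did not pass (637 up and 116 down adjusted over the list alone). This direction nearly vanished under quantile normalization, where the median was 0.0550, with 349 up and 301 down. Named non-coding RNAs had a median log2 fold change of 1.17 (adjusted p = 0.0181, or 0.243 with an estimated correlation). Under quantile normalization it was 0.47 (21 up, 9 down). Of 44, 32 rose, 6 fell and 6 did not pass, among them sme2 (11.2 ± 0.725 to 48.3 ± 2.83 CPM, log2 2.11 ± 0.079), omt3 (3.10 ± 0.075) and ter1 (0.74 ± 0.022). Under every agent the list also holds mrl1 (1.07 ± 0.046 here), whose ID is that of a protein-coding gene. At 10 CPM or more, meu3 (5.09 ± 0.27), SPNCRNA.1514 (4.79 ± 0.28) and SPNCRNA.472 (3.48 ± 0.090) rose most and SPNCRNA.873 (-2.01 ± 0.16), SPNCRNA.1297 (-1.77 ± 0.11) and SPNCRNA.703 (-1.65 ± 0.12) fell most. All 3 Tf2 elements rose, with a median of 1.69 (adjusted p = 0.00384, or 0.0862 with an estimated correlation). Other large single rises were osr1 (28.6 ± 0.574 to 451 ± 3.75 CPM, log2 3.98 ± 0.029), nrg1 (3.97 ± 0.071), smp2 (3.83 ± 0.19), ftm6 (8.39 ± 0.31) and ftm2 (5.76 ± 0.24), and other falls were alr2 (-3.34 ± 0.13), ddr48 (-2.37 ± 0.068) and the sulphate transporter gene sul2 (349.6 ± 7.57 to 45.9 ± 0.606 CPM, log2 -2.93 ± 0.036). Of 35 core stress genes 12 rose, 21 fell and 2 did not pass, adjusted p = 0.765. Rises included tms1 (2.28 ± 0.039) and gst2 (2.42 ± 0.016), and falls included ish1 (-0.94 ± 0.019), hsp9 (-0.46 ± 0.015), gpd1 (-0.75 ± 0.017) and ctt1 (-0.29 ± 0.019). Of 27 chaperone genes 10 rose, 15 fell and 2 did not pass, adjusted p = 0.139. Rises included hsp20 (1.36 ± 0.028) and hsp16 (0.65 ± 0.017), and falls included pss1 (-1.20 ± 0.016) and mas5 (-1.06 ± 0.021). Of 24 Pap1 genes 10 rose, 11 fell and 3 did not pass, adjusted p = 0.0841. A rise was seen in tpx1 (1.59 ± 0.016) and a fall in apt1 (-1.92 ± 0.031). In the iron list 11 rose, 8 fell and 1 did not pass, adjusted p = 0.616. Falls included str1 (-2.28 ± 0.030) and frp1 (-1.41 ± 0.031). In the respiration list 17 rose, 9 fell and 7 did not pass, adjusted p = 0.0556. Rises included sdh2 (0.93 ± 0.020) and cox9 (1.13 ± 0.038). Starvation genes did not pass as a list, and 27 rose, 16 fell and 9 did not pass, adjusted p = 0.662. Among amino acid genes 19 rose, 22 fell and 6 did not pass, adjusted p = 0.708. Among heterochromatin genes 15 rose, 4 fell and 3 did not pass, adjusted p = 0.293. Among telomeric genes 11 rose, 4 fell and 4 did not pass, adjusted p = 0.243. Among phosphate genes 7 rose and 6 fell, adjusted p = 0.872.

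**Figure D3:**
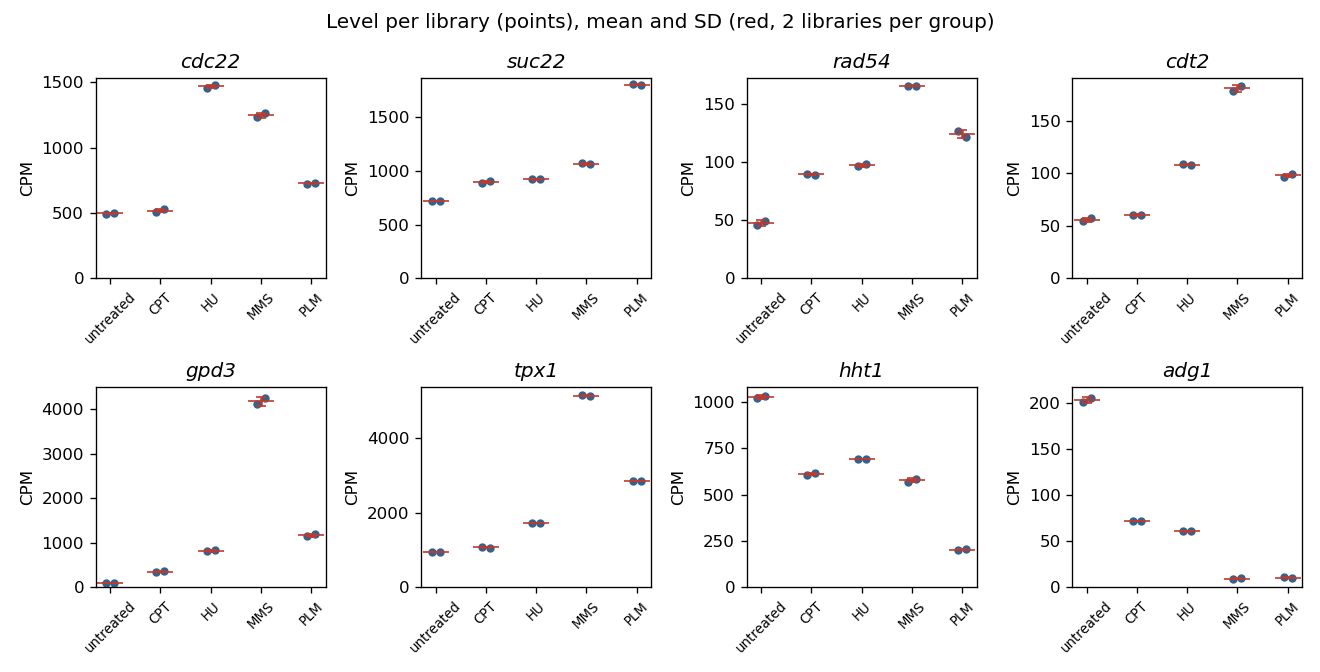
Level in CPM of 8 named genes in each library (blue points, 2 per group), with the mean and SD of each group in red, in untreated cells and after camptothecin (CPT), hydroxyurea (HU), MMS and phleomycin (PLM). The gene cdc22 was highest with hydroxyurea, suc22 with phleomycin, cdt2, rad54, gpd3 and tpx1 with MMS, and hht1 was lowest with phleomycin, and adg1 was lowest with MMS and phleomycin.

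Over the 27 lists and 4 comparisons, 53 of 108 list results passed with the preset correlation and 15 with an estimated one. The 15 were the long non-coding RNAs in all 4 comparisons, MBF genes with hydroxyurea and MMS, purine and pyrimidine genes with camptothecin and MMS, ribosome biogenesis with camptothecin and phleomycin, glucose-repressed genes with camptothecin, meiosis genes with hydroxyurea, iron and Pap1 genes with MMS, and histones with phleomycin. By fry, which asks whether the genes of a list move one way on balance and sets them against no other genes, 102 of 108 passed. The signs of median, mean and camera direction differed in 13 list results, none of which passed with the preset correlation. They were the checkpoint, chaperone, MBF, starvation, phosphate and telomeric lists with camptothecin, glucose-repressed and phosphate genes with hydroxyurea, glucose-repressed and heterochromatin genes with MMS, and amino acid, chaperone and Pap1 genes with phleomycin. Medians of lists that did not pass also changed sign under quantile normalization or total count scaling: with camptothecin those of checkpoint, repair, heterochromatin, MBF, starvation and telomeric genes, and with hydroxyurea those of amino acid, respiration, mitosis, starvation, phosphate and ribosome biogenesis genes. With MMS these were amino acid, repair, heterochromatin, meiosis and telomeric genes, and with phleomycin amino acid, checkpoint and Pap1 genes. A last list, of antisense RNAs, had 1 member, cti6-antisense-1, and was not tested as a list; it rose with MMS (2.15 ± 0.18), phleomycin (3.05 ± 0.17), camptothecin (0.63 ± 0.21) and hydroxyurea (0.67 ± 0.20), where quantile normalization turned it.

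**Figure D4:**
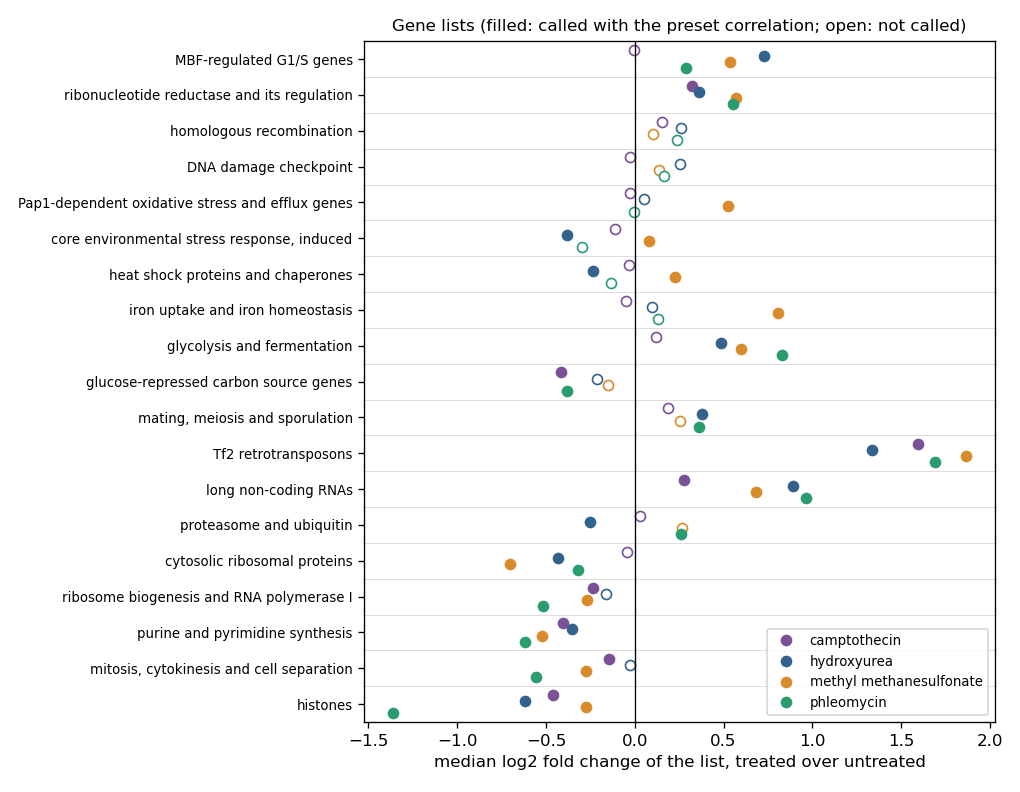
Median log2 fold change, treated over untreated, of 19 gene lists under each agent, filled where the list passed with the preset correlation and open where it did not. MBF genes lie highest with hydroxyurea (0.73), iron genes with MMS (0.81) and glycolysis genes with phleomycin (0.83), and histones lie lowest with phleomycin (-1.36). Among the filled points, under quantile normalization the medians of long non-coding RNAs with camptothecin and of chaperones with hydroxyurea change sign.

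Non-coding features rose more in the median than sets of protein-coding genes matched on level. Their median log2 fold change over 1016 tested features was 0.28 with camptothecin, 0.89 with hydroxyurea, 0.68 with MMS and 0.96 with phleomycin. Medians of 10000 random sets of protein-coding genes of the same size and level were 0.13, 0.36, 0.24 and 0.41 in the same order, and the non-coding median lay above every such set in each comparison (percentile 100). Quantile normalization turned the camptothecin median to -0.04, still above its matched sets at -0.15. Below 1 CPM the order was reversed with camptothecin, with medians of 0.285 for 230 non-coding and 0.319 for 111 protein-coding features. By 2-fold or more, 18.3, 41.7, 38.6 and 46.8 % of non-coding features rose, against 11.3, 23.8, 24.2 and 32.5 % in the matched sets and 3.82, 6.10, 8.05 and 9.94 % of all protein-coding genes tested.

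Non-coding features and the protein-coding genes they overlap changed together only weakly. Reads over a shared span may have been left out of the counts, whatever the strand. The values of overlapping pairs may therefore cover only the parts outside the overlap. Over 750 such pairs, Spearman's rho across pairs was 0.178 with camptothecin (permutation p = 0.0001, the smallest 10000 pairings can give), 0.0768 with hydroxyurea (permutation p = 0.0329), 0.112 with MMS (permutation p = 0.0025) and 0.102 with phleomycin (permutation p = 0.0067). Adjusted over the 4 comparisons, the permutation p was 0.0004, 0.0329, 0.005 and 0.00893. Over 947 pairs of a non-coding feature with the nearest gene it does not overlap, rho was 0.163, 0.128, 0.158 and 0.138. Pairs are not independent replicates, and with antisense pairs alone rho no longer passed for hydroxyurea, MMS and phleomycin. In antisense pairs with both members at 5 CPM or more it passed for MMS (0.192, adjusted p = 0.022) and phleomycin (0.156, adjusted p = 0.0386) but not hydroxyurea (0.0771). Same-strand pairs gave 0.301 with camptothecin, 0.278 with MMS and 0.222 with phleomycin, all past the threshold, and 0.156 with hydroxyurea, which was not.

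Many of the same features changed under all 4 agents. Together 940 rose and 1092 fell in every comparison, where independent lists would share 136 and 133. In 20 simulations of unchanged groups against the same 2 untreated libraries a comparison had at most 1 call, so their overlap of 0 (edgeR) decides nothing here. By 2-fold or more, 197 rose (77 protein-coding and 120 non-coding) and 11 fell, the latter being sul2, the cell separation genes adg1 and agn1, inv1, alr2, the amino acid permease gene aat1, apt1, SPAC27D7.11c, SPBPB7E8.01, SPNCRNA.1313 and SPNCRNA.427. The balance depends on the scaling: 1113 rose and 824 fell in all 4 under total count scaling, and 718 and 1008 under quantile normalization. By 2-fold or more these settings gave 217 up and 4 down, and 72 up and 25 down. Log2 fold changes correlated across features with r = 0.857 between hydroxyurea and phleomycin, 0.823 between MMS and phleomycin, 0.766 between hydroxyurea and MMS, 0.632 between camptothecin and phleomycin, 0.604 between camptothecin and hydroxyurea and 0.536 between camptothecin and MMS. Simulated unchanged groups gave r between 0.502 and 0.516, with a covariance near 0.0102 against 0.379 to 0.871 observed. With a different untreated library in each comparison of a pair, the covariance was 0.936 to 0.975 times that with the same one. The overlaps were not split in this way, since each part would hold 1 untreated library, and some of their excess may come from the shared controls.

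Tested directly against each other, the agents differed in most features. Camptothecin and hydroxyurea differed in 4164 features (131 higher with camptothecin and 421 with hydroxyurea by 2-fold or more), camptothecin and MMS in 4408 (278 and 493), and camptothecin and phleomycin in 4590 (226 and 636). Hydroxyurea and MMS differed in 4218 (245 higher with hydroxyurea and 210 with MMS), hydroxyurea and phleomycin in 4081 (114 and 239), and MMS and phleomycin in 4126 (123 and 270). Few features moved 2-fold or more in opposite directions, between 2 and 10 per pair of agents. The iron transporter gene str3 did so in every pair with camptothecin, falling by 3.06 there and rising by 1.46 with hydroxyurea, 5.49 with MMS and 1.08 with phleomycin. Between hydroxyurea and MMS the 3 were SPAC212.06c, SPBPB8B6.02c and srx1, which fell by 1.15 with hydroxyurea and rose by 2.33 with MMS. Between hydroxyurea and phleomycin the 2 were SPNCRNA.70 and the copper transporter gene ctr4, which rose by 1.16 with hydroxyurea and fell by 2.01 with phleomycin. The ferric reductase gene frp1 rose by 1.84 with MMS and fell by 1.41 with phleomycin, and mfm2 rose by 1.90 with camptothecin and fell by 2.52 with MMS; these features were chosen after their values were seen. The split by agent depends on the scaling. Of features 2-fold or more apart, the percent higher with the first agent changed under quantile normalization from 23.7 to 42.7 for camptothecin over hydroxyurea, from 36.1 to 46.6 for camptothecin over MMS, and from 26.2 to 46.9 for camptothecin over phleomycin. It changed from 53.8 to 46.4 for hydroxyurea over MMS, from 32.3 to 45.1 for hydroxyurea over phleomycin and from 31.3 to 49.5 for MMS over phleomycin. Over all differing features, total count scaling changed it from 49.8 to 27.3 for camptothecin over hydroxyurea, from 53.6 to 63.4 for hydroxyurea over MMS and from 53.2 to 65.0 for hydroxyurea over phleomycin.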

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

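The contrasts between agents were planned, while the criterion of opposite 2-fold changes and the choice of genes were set only after the results were seen. Features that passed the threshold and changed 2-fold or more in opposite directions under a pair of agents stand out, and the difference itself was tested by an edgeR contrast between the agents. There were 7 between camptothecin and hydroxyurea, 10 between camptothecin and MMS, 8 between camptothecin and phleomycin, 3 between hydroxyurea and MMS, 2 between hydroxyurea and phleomycin, and 6 between MMS and phleomycin. Among those of these features that are protein-coding genes with a symbol, the iron transporter gene str3 differed most in each pair with camptothecin, with a log2 fold change of camptothecin minus the other agent of -4.52 for hydroxyurea, -8.55 for MMS and -4.14 for phleomycin. By the same choice, the sulphiredoxin gene srx1 differed by -3.48 (hydroxyurea minus MMS), the copper transporter gene ctr4 by 3.17 (hydroxyurea minus phleomycin), and the ferric reductase gene frp1 by 3.26 (MMS minus phleomycin). No technical or biological explanation was tested for these.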

How the results depend on the processing

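Total count scaling, leaving out features covered for 75 % or more, and 2-fold counts under other settings were chosen only after the results were seen. Most named genes were chosen for large changes or small adjusted p in the main fit, which favours their passing under other settings too. Their stability is therefore no measure for features in general. Of 476 named gene results, 462 kept their direction and their side of the threshold under all settings but the fold threshold, and 6 reversed under a scaling. Under quantile normalization these were cti6-antisense-1 (-0.22), gpd1 (0.051), hsp16 (0.29) and rad52 (-0.25) with hydroxyurea, gpd1 with MMS (0.13) and rad52 with phleomycin (-0.32), and hsp16 with hydroxyurea was 0.053 under total count scaling. With a fold change of 2 or more required, the counts fell by construction to 450, 778, 1004 and 1260 for camptothecin, hydroxyurea, MMS and phleomycin, and for long non-coding RNAs to 218, 442, 435 and 502. Between agents they were 552 (camptothecin and hydroxyurea), 771 (camptothecin and MMS), 862 (camptothecin and phleomycin), 455 (hydroxyurea and MMS), 353 (hydroxyurea and phleomycin) and 393 (MMS and phleomycin), and 208 were shared by all 4 agents. With a mean of 5 CPM or more, fewer features are tested, and long non-coding RNAs past the threshold numbered 316, 383, 374 and 367. Features at 2-fold or more then numbered 248, 391, 587 and 745 against untreated cells, 286, 452, 480, 262, 147 and 226 between agents in the same order, and 94 in all 4. Quantile normalization left 511 features at 2-fold or more with hydroxyurea and 97 in all 4, and the cause was not tested. Without covered features, fewer tested by construction, 463 long non-coding RNAs passed with MMS and 494 with phleomycin, 211 features differed 2-fold or more between hydroxyurea and phleomycin, and 128 were 2-fold or more in all 4. Of 108 list results, 53 passed, against 15 with an estimated correlation and 102 by fry. Numbers of lists given below are likewise numbers of list results out of 108. For pairs of a non-coding feature and the gene it overlaps, rho was 0.0591 (hydroxyurea), 0.0752 (MMS) and 0.0691 (phleomycin) over antisense pairs and 0.0805 with hydroxyurea at 5 CPM or more, none past the threshold, and the cause was not tested. Antisense pairs at 5 CPM or more gave 0.192 with MMS (adjusted p = 0.022) and 0.156 with phleomycin (adjusted p = 0.0386), both past it. With a replicate block, a pairing that the libraries do not show, 54 of the 108 list results passed and 1963 features were shared by all 4. Long non-coding RNAs with camptothecin no longer passed (adjusted p = 0.0666), while glycolysis with camptothecin (adjusted p = 0.0120) and respiration with phleomycin (adjusted p = 0.0475) did. Leaving out 1 library at a time, where the lone library of a group is assumed to vary like the others, gave 3781 to 4083, 4257 to 4537, 4379 to 4622 and 4557 to 4766 features past the threshold in the 4 comparisons, 52 to 59 lists, and 1847 to 2023 shared features.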

Other observations

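The tests of level, of scaling and both tests of counts near 0 were chosen only after the results were seen, as were the agent-specific features given first, and the covariance test was added after the overlap was seen, with its bounds set before its own value. Features 2-fold or more from untreated cells and also 2-fold or more from each other agent, in 1 direction, numbered 50 up (32 protein-coding) and 20 down with camptothecin, 11 and 1 with hydroxyurea, 41 (26 protein-coding) and 10 with MMS, and 66 (28 protein-coding) and 8 with phleomycin. Under other settings these counts ranged from 35 to 53, 8 to 25, 3 to 17, 0 to 3 (hydroxyurea down, where edgeR gave 0 under total count scaling and without covered features, and quantile normalization gave 3), 33 to 56, 3 to 23, 21 to 71 and 8 to 32. With camptothecin these included rises of cmt2 and yhb1 and falls of the peptide transporter gene ptr2 and sod1. Other agents moved some of them the same way by less: yhb1 rose 2-fold or more under all 4, cmt2 rose by 2.33 (log2) with MMS, and ptr2 fell by 1.10 with MMS and 1.23 with phleomycin. With MMS they included rises of shu1, str3, fio1, fip1, the ferric reductase gene frp2, the riboflavin synthesis gene rib4 and the metallothionein gene zym1, and a fall of srb11, a Mediator cyclin gene. Of these, frp2 and zym1 rose 2-fold or more under all 4, shu1 rose by 2.27 with hydroxyurea and 3.94 with phleomycin, str3 by 1.46 and 1.08, and fip1 by 1.44 with phleomycin. With phleomycin they included rises of the spore formation gene spo5 and gep4, and falls of the copper transporter genes ctr4 and ctr5 and the histone genes hht1, hta2 and hhf1. Here too spo5 rose by 1.03 with hydroxyurea and 1.31 with MMS, ctr5 fell by 1.04 with MMS, and the 3 histone genes fell under every agent.

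Genes of the mitochondrial genome fell in part under each agent. Of 10 tested, 2 rose and 6 fell with camptothecin, 7 fell with hydroxyurea, 1 rose and 5 fell with MMS, and 5 fell with phleomycin, with median log2 fold changes of -0.17, -0.40, -0.092 and -0.10.

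Non-coding features rose more than protein-coding genes, and neither their low level nor the scaling accounts for all of this: the smallest excess over level-matched protein-coding sets in the 4 comparisons was 0.153 (log2), 0.137 without covered features, and 0.115 under quantile normalization. These smallest values are those of camptothecin. Without covered features the excess went from 0.531 to 0.363 with hydroxyurea, from 0.442 to 0.408 with MMS and from 0.557 to 0.401 with phleomycin. Below 1 CPM with camptothecin there was no excess (0.285 against 0.319). An equal addition of reads to every feature, as from genomic DNA, was tested first by the ratio of the excess at 5 to 20 CPM to that at 0.2 to 1 CPM, whose smallest value of 2.08 lay between the bounds set for it and decided nothing. A second test was added for that reason, with its bounds set before its result: of 50 quiet non-coding features that nothing overlaps, at least 46 % gained little of the median excess, where an equal addition would leave few such features, although poor mappability of some of them was not tested. A change in transcription or decay of non-coding RNA under the agents remains open as a hypothesis and could not be tested here.

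The same features changed under all 4 agents, and chance values of the shared untreated libraries are argued against as the whole cause: with a different untreated library in each of 2 comparisons, the covariance of log2 fold changes across features was at least 0.936 times that with the same library. Part of the overlap may still come from the shared controls, and a state common to both untreated libraries is not tested by this. An untreated library that stands apart is argued against too, since without either of them at least 199 features were 2-fold or more in 1 direction in all 4. A response common to the agents, or a difference in handling of untreated cells, whose time in culture the labels do not give, may each lie behind this and cannot be separated in this design.

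Genes with counts near 0 may reflect reads left out where features overlap: protein-coding genes wholly covered by opposite-strand features had a median 0.000172 times that of genes without overlap. Weak expression is argued against, since covered genes of the proteasome, ribosome biogenesis and ribosomal protein lists stood at 1.48e-05 times the level of uncovered members. The counting tool and its strand setting are not given, so this remains a hypothesis.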
